A study of Mus musculus with 22 samples.

How the data were processed

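Gene expression was measured by RNA sequencing of gastrocnemius muscle from 22 BALB/c mice, 10 male and 12 female, in 8 groups given by sex, injection and activity. The injection was either C26 colorectal cancer cells or phosphate-buffered saline (PBS), and mice were either sedentary or trained by progressive weighted wheel running (PoWeR). The deposited table held 17725 genes by 22 libraries, and each library was assigned to its group from its title. The deposited values are a signal: gene counts that the authors had divided by 1 scale factor per library. The submitters' processing notes name STAR 2.7.8a, the mouse genome build mm39, Partek and DESeq2, without stating which of the last 2 made the counts or the scaling. Of the low values (up to 200 steps of the smallest size), 72.6% to 77.9% were whole multiples of 1 step per library within 0.02 of a step in 21 libraries, and 85.9% were in male C26 trained 1. Whole reads were therefore not recovered, and the count tests planned for whole reads (edgeR and DESeq2) were not run. Dividing each library's total by its step gave an estimate of 12.2 to 20.8 M reads (M, 1e6) per library, and the deposited totals lay between 14.3 and 17.9 M.

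Gene identifiers were paired with symbols through an annotation of the earlier mouse build, which gave a symbol to 17689 of the 17725 identifiers. Since the values were made on mm39, no positions were taken from that annotation. Values were taken as log2(value + 1). The 14531 genes with a mean value of at least 10 over the 22 libraries were fitted in R 4.3.3 with limma 3.58.1, with a mean for each of the 8 groups and an intensity trend in the prior variance, which left 14 residual degrees of freedom. Fold changes are log2 differences between group means with their standard errors (SE), p-values are two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 14531 genes of a comparison. Sex-averaged comparisons weighted males and females equally. Each interaction was a contrast of the same fit. All labels put the libraries in batch 1, so no comparison within batches was needed. The replicate numbers of the titles were tested as a pairing. Residuals of the 71 library pairs with the same number had a median correlation of 0.0287 across genes, against -0.0145 for the other 140 pairs. The highest same-number correlation was 0.368, and 12 of the 22 libraries correlated best with one of their own number. The numbers were not treated as pairs, though a weak link is not excluded, and the fit with the replicate number as a block is an alternative.

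The groups, the comparisons, 26 gene lists, 14 marker lists of other cell types and of sex, 40 focus genes and the alternatives were chosen before the data were examined. Lists with at least 5 tested members, 36 in all, were tested with camera in limma at a preset correlation of 0.01 between genes over the 5 sex-averaged comparisons, and the p-values of all 180 tests were adjusted together. Of these tests, 80 passed at the preset correlation and 0 passed with an estimated correlation, so every list call rests on the preset value. Members of a list were also counted when adjusted over the list alone. Genes were named by a rule: up to 8 called genes per direction with the largest fold change, a mean of at least 50 and the same sign in both sexes (5 per direction for interactions and for comparisons within a sex), up to 3 called members of each list by smallest adjusted p or its most abundant member when none passed, and the focus genes, of which 39 were tested. Other genes are marked where they were chosen after the values were seen. For each named gene, the libraries lying on the side of its fold change were counted against the mean of the reference libraries of the same sex. Called genes were picked in the same libraries, so these counts describe the spread between libraries and give no independent support.

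A tumour response score was computed for each library as the signed mean log2 change from the PBS sedentary mean of its own sex, over the genes called for the tumour in sedentary mice of the other sex. Trained and sedentary tumour-bearing mice were compared by an exact two-sided permutation test within sex. The alternatives were a pseudocount of 4, no filter, a mean of at least 50, median-of-ratios and upper-quartile rescaling, the replicate block, limma's array weights, a fit of the compared groups only, and each library left out in turn. For the lists they were an estimated correlation and fry, and for the score the 100 genes of smallest p. The default estimator of the array weights did not converge, and the gene-by-gene estimator was used. Fits without male C26 trained 1 for comparisons that do not hold it, and a fit of the 12 female libraries alone, were chosen after the data were seen. The fit was tested on simulated data: of 100 genes changed by 1 on the log2 scale, the sex-averaged comparisons called between 51 and 72, and of 100 changed by 2, between 67 and 88, with 7 to 9 calls among the unchanged genes. At a change of 1, comparisons within a sex called 33 to 56, sex by tumour 24 and sex by training 19. The simulation gave a gene the same spread in all libraries, so it held no library like male C26 trained 1. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.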

Results

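Gastrocnemius muscle was sequenced from mice that carried the C26 tumour, a transplanted colorectal cancer line of BALB/c mice, or had received saline (PBS), and that had either been sedentary or trained with PoWeR, voluntary running on a wheel with increasing weight. Mice were 7 weeks old at acclimation, trained for 8 weeks before the injection and for 3.5 weeks after it, and muscle was taken 25 days after the injection. Of the 8 groups of sex, injection and activity, 6 held 3 mice and 2 held 2 mice (male C26 sedentary and male C26 trained). The table listed 14.3 to 17.9 M normalized counts per library from an estimated 12.2 to 20.8 M reads (M, 1e6). Mitochondrial transcripts made up 10.6% to 14.2% of the total in the 5 C26 sedentary libraries and 17.6% to 18.5% in the 3 female C26 trained libraries, against 12.9% to 19.6% in the 12 PBS libraries. The male C26 trained libraries held 10.8% and 9.26%.

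Male C26 trained 1 stood apart from the other libraries. It listed 5730 of the 17725 genes (32.3%) at 0, where the other 21 libraries listed 173 to 644, and only 793 of its genes lay between 1 and 20 estimated reads, against 4116 to 5076. Its median Spearman correlation with the other libraries, across genes, was 0.869, against 0.947 to 0.982. The first principal component held 60.05% of the variance with this library and 29.3% without it. Since the fit shares its variance over all groups, the counts of every comparison are also given without this library. It also lowered the median fold change over all genes, to -0.10 for training in tumour-bearing mice, -0.12 for the tumour in trained mice and -0.13 for their interaction. In males alone the median was -0.16 for training with the tumour and -0.19 for the tumour in trained mice, and it was 0.18 for the sex by training difference. Those medians are not an offset shared by all genes. The share of genes listed at 0 in this library was 51.1% at mean values of 20 to 60 in the other libraries and 4.39% at 150 to 400. In the other comparisons, and in all comparisons without this library, the median lay between -0.05 and 0.02.

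**Figure D1:**
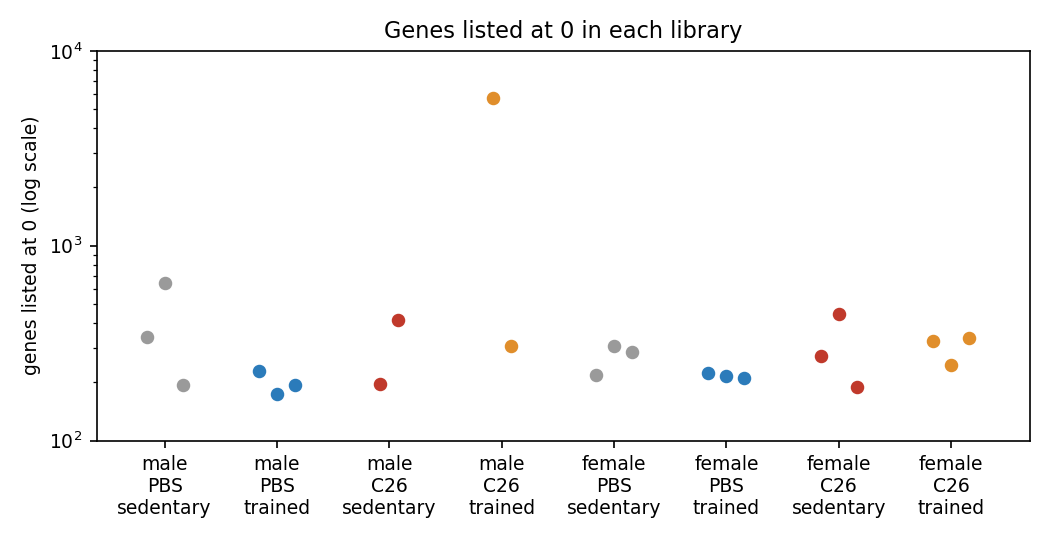
Number of genes listed at 0 in each of the 22 libraries, by group, on a log axis, with 1 point per library. Male C26 trained 1 lies at 5730 genes and the other 21 libraries between 173 and 644.

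The first comparison asked what the tumour did to the muscle of sedentary mice (5 C26 against 6 PBS libraries, sexes averaged). Acute phase genes and the metallothioneins were among the genes that rose most. Lcn2 (ENSMUSG00000026822), an iron-carrier binding protein of the acute phase, rose by 5.74 ± 0.52 on the log2 scale (SE, adjusted p = 2.14e-06). Its level went from 18.7 ± 14.7 to 1338 ± 499.8 normalized counts in males (SD; n = 3 and 2) and from 13.8 ± 5.69 to 676 ± 456 in females (n = 3 and 3). The metallothioneins Mt2 and Mt1, which bind zinc and copper, rose by 5.72 ± 0.43 and 5.0 ± 0.45. The secreted protease inhibitor Serpina3n rose by 4.82 ± 0.34, the haemoglobin-binding Hp by 3.92 ± 0.49, the cytokine-signalling inhibitor Socs3 by 3.8 ± 0.40, the interleukin-6 receptor Il6ra by 3.08 ± 0.35 and the transcription factor Junb by 3.07 ± 0.52. Nmrk2, a nicotinamide riboside kinase that feeds NAD synthesis, changed most in the other direction, by -4.72 ± 0.39 (adjusted p = 9.65e-07). It was followed by the immunoglobulin chain Ighm (-4.34 ± 0.42), the cartilage matrix genes Chad (-3.92 ± 0.54) and Cilp2 (-3.59 ± 0.61), the transferrin receptor Tfrc (-3.45 ± 0.40), the proteoglycan Kera (-3.31 ± 0.53), Nrep (-3.25 ± 0.32) and the secreted muscle peptide Ostn (-3.12 ± 0.43). Over all genes, 1519 rose and 1636 fell (limma). Of the 114 named genes that passed, 112 lay on the side of their fold change in each of the 5 C26 libraries, and Hspd1 and Rgs5 did so in 4 of 5. Without male C26 trained 1, which is in neither group, 5251 genes passed, 3154 of them shared, and without male C26 sedentary 2, 1671 passed. Array weights called 5439 genes, and leaving out 1 of the 11 compared libraries ended between 249 and 1501 of the 3155 calls.

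Genes of protein breakdown rose in the same mice. Of 25 atrophy-related ubiquitin ligases and FoxO targets, 16 rose and 1 fell (median 1.14, camera adjusted p = 1.41e-07, adjusted p = 0.311 with an estimated correlation), and adjusted over the list alone 17 rose and 2 fell. The muscle ubiquitin ligases Trim63 and Fbxo32 rose by 2.46 ± 0.48 (adjusted p = 0.00149) and 2.24 ± 0.37 (adjusted p = 0.000366), Foxo1 by 1.63 ± 0.29, Eif4ebp1, a repressor of translation initiation, by 2.72 ± 0.25, and Eda2r by 1.38 ± 0.47. The call of Eda2r ended with the replicate block. Of 32 proteasome subunits 22 rose (median 0.34, camera adjusted p = 1.87e-14, adjusted p = 0.354 with an estimated correlation, 27 adjusted over the list alone). In the list of autophagy and lysosome genes, 14 of 27 rose (median 0.32, camera adjusted p = 1.05e-05, adjusted p = 0.311 with an estimated correlation, 15 adjusted over the list alone). Map1lc3b of the autophagosome membrane (1.19 ± 0.12), the mitophagy receptor Bnip3 (0.98 ± 0.19) and Sqstm1 (0.83 ± 0.18) were among them. The ribosome biogenesis list had 13 of 26 higher (median 0.35, camera adjusted p = 5.55e-06, adjusted p = 0.416 with an estimated correlation, 16 adjusted over the list alone). Myc, a driver of ribosome production, rose by 2.21 ± 0.30.

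Genes of cytokine and hormone responses moved with them. Of 25 genes of interleukin-6, STAT3 and the acute phase, 18 rose and 1 fell (median 1.78, camera adjusted p = 5.22e-18, adjusted p = 0.129 with an estimated correlation, 20 and 1 adjusted over the list alone). Stat3 rose by 1.78 ± 0.15 and the oncostatin M receptor Osmr by 1.49 ± 0.12. Glucocorticoid-responsive genes had 11 higher and 1 lower of 21 (median 0.81, camera adjusted p = 3.81e-07, adjusted p = 0.354 with an estimated correlation, 14 and 1 adjusted over the list alone). The co-chaperone Fkbp5 was at 2.33 ± 0.22 and Cebpd at 3.0 ± 0.48. In the NRF2 and antioxidant list 15 rose and 2 fell of 24 (median 0.43, camera adjusted p = 2.36e-06, adjusted p = 0.311 with an estimated correlation, 16 and 2 adjusted over the list alone). Gpx3 of that list, a secreted glutathione peroxidase, rose by 1.69, while Sod2, the mitochondrial superoxide dismutase, fell by 0.73. Markers of macrophages, neutrophils and fat cells were also higher, while the B cell marker Ighm fell. Macrophage markers had 7 of 13 higher (median 1.06, camera adjusted p = 1.47e-05, adjusted p = 0.383 with an estimated correlation, 7 adjusted over the list alone). The scavenger receptor Cd163 rose by 1.44 ± 0.18. Neutrophil markers had 4 of 5 higher (median 3.16, camera adjusted p = 1.57e-05, adjusted p = 0.311 with an estimated correlation, 5 adjusted over the list alone). S100a8 rose by 4.1 ± 0.49 and Csf3r, a growth factor receptor, by 2.68 ± 0.31. Adipocyte markers had 4 of 12 higher (median 0.66, camera adjusted p = 0.0058, adjusted p = 0.44 with an estimated correlation, 4 adjusted over the list alone). The lipid-droplet coat gene Plin4 rose by 1.5 ± 0.11.

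Genes of energy metabolism fell. Of 64 oxidative phosphorylation genes 38 fell and 0 rose (median -0.40, camera adjusted p = 1.8e-13, adjusted p = 0.538 with an estimated correlation, 44 adjusted over the list alone). Ndufs1 of complex I was at -0.82 ± 0.12. Of 17 citric acid cycle genes 14 fell (median -0.52, camera adjusted p = 3.93e-10, adjusted p = 0.425 with an estimated correlation, 15 adjusted over the list alone). Idh3a was at -0.91 ± 0.09 and Dlat of the pyruvate dehydrogenase complex at -1.01 ± 0.12. The list of mitochondrial regulators and exercise-responsive factors had 16 lower and 1 higher of 27 (median -0.48, camera adjusted p = 3.21e-05, adjusted p = 0.354 with an estimated correlation, 16 and 3 adjusted over the list alone). Vegfa, an angiogenic growth factor of that list, was at -0.62 ± 0.12, while the coactivator Ppargc1a, at -0.48, did not pass. Glycolysis and glycogen genes had 12 lower and 3 higher of 23 (median -0.34, camera adjusted p = 0.00248, adjusted p = 0.492 with an estimated correlation, 12 and 3 adjusted over the list alone). Tpi1 was at -0.74 and Pkm at -0.69. Calcium handling genes had 11 lower and 1 higher of 22 (median -0.43, camera adjusted p = 3.86e-05, adjusted p = 0.468 with an estimated correlation, 14 and 1 adjusted over the list alone). Casq1, the calcium store of fast fibres, was at -1.59 ± 0.24. The share of mitochondrial transcripts was 10.6% to 14.2% in these C26 libraries and 12.9% to 19.6% in the PBS libraries of both activities.

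Matrix genes fell too. Of 34 extracellular matrix genes 14 fell and 1 rose (median -0.42, camera adjusted p = 0.000431, adjusted p = 0.62 with an estimated correlation, 16 and 1 adjusted over the list alone). The fibrillar collagen Col1a1 was at -1.62 ± 0.30 and Col15a1 at -0.99 ± 0.12. Tendon markers had 5 of 10 lower (median -2.03, camera adjusted p = 0.000874, adjusted p = 0.538 with an estimated correlation, 5 adjusted over the list alone). The remaining lists did not pass camera. Counts of higher and lower members, with the median, were 1 and 2 of 27 for fatty acid uptake and oxidation (-0.15), 0 and 0 of 15 for slow fibre genes (-0.37), 1 and 4 of 15 for fast fibre genes (-0.29). They were 6 and 4 of 24 for the sarcomere (0.16), 1 and 2 of 30 for interferon response (-0.28), and 1 and 1 of 14 for NF-kB (0.15). They were 2 and 4 of 17 for the neuromuscular junction (-0.27), 2 and 1 of 18 for myogenic factors (-0.10). For ATF4 targets they were 5 and 2 of 23 (0.19), for the clock 4 and 3 of 18 (0.02), for heat shock 1 and 3 of 22 (-0.03) and for amino acid catabolism 1 and 5 of 21 (-0.10). The myostatin, activin and TGF-beta list had 6 higher and 4 lower of 28, with a median of -0.05 but a mean of 0.12 and an upward test, and heat shock genes had a mean of 0.03 with a downward test. Among markers, the counts were 2 and 3 of 13 for endothelium (-0.14), 2 and 1 of 13 for fibro-adipogenic cells (-0.17). They were 0 and 2 of 12 for smooth muscle (-0.15), 1 and 0 of 11 for Schwann cells (median -0.06 with an upward test), 0 and 1 of 7 for red blood cells (0.42) and 0 and 0 of 5 for dividing cells (-0.41). Lists with under 5 tested genes were not tested as lists: the only T and NK cell marker, Cd247, was at 0.02 ± 0.47. The only B cell marker was Ighm, given above. Of the 4 epithelial markers Krt18 was at 0.96 ± 0.57, Cdh1 at 0.65 ± 0.71, Elf3 at -0.02 ± 0.65 and Lgals4 at 0.24 ± 0.73. Adjusted over the list alone, the counts of higher and lower members of these lists differed for fatty acid oxidation (0 and 1), fast fibre genes (1 and 6), the neuromuscular junction (3 and 6), amino acid catabolism (2 and 7) and Schwann cells (0 and 0), and were otherwise equal. Myostatin (Mstn, 0.67, adjusted p = 0.198), Pdk4 (1.10, adjusted p = 0.157), Klf15 (0.60, adjusted p = 0.0731), Fbxo30 (0.03), Myh7 (-0.13) and Myh4 (-0.29) did not pass.

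**Figure D2:**
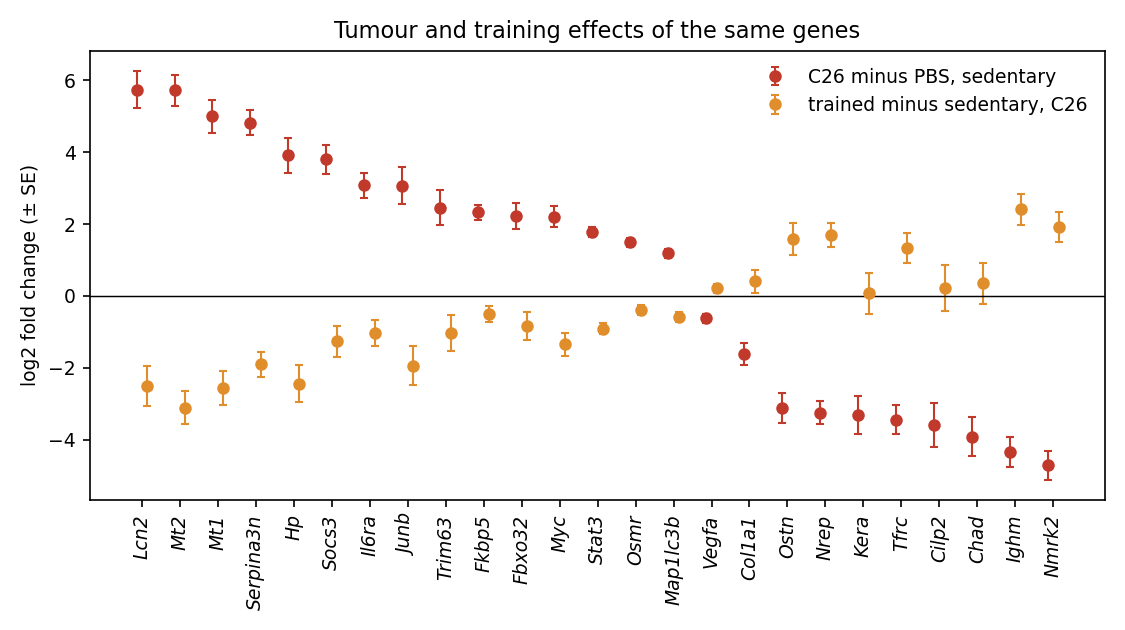
Log2 fold change ± SE of 25 named genes for the tumour in sedentary mice (5 C26 against 6 PBS libraries) and for training in tumour-bearing mice (5 trained against 5 sedentary libraries), sexes averaged. Lcn2 lies at 5.74 and -2.51 and Nmrk2 at -4.72 and 1.91.

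Within each sex, the tumour changed many of the same genes. In males, Lcn2 rose by 6.28 ± 0.77 (adjusted p = 0.00017), Mt2 by 5.71 ± 0.64 and Serpina3n by 4.23 ± 0.51. There, Nmrk2 (-5.32 ± 0.59), Chad (-4.92) and Ighm (-4.79) were lower. In females, Mt2 rose by 5.72 ± 0.58 (adjusted p = 3.52e-05), Serpina3n by 5.41 ± 0.46, Hp by 5.21 ± 0.65 and Lcn2 by 5.21 ± 0.69, while Nmrk2 (-4.13 ± 0.53), Ighm (-3.90) and Nrep (-3.16) were lower. The fit called 924 genes higher and 864 lower in males and 605 higher and 648 lower in females. Of these, 330 were higher in both and 342 lower in both, where independent lists would share 38.5 each, and 2 were called in opposite directions. All 98 named genes that passed in males lay on that side in both C26 libraries, and all 95 in females in the 3 C26 libraries. The difference between the sexes was called for 0 genes (limma, 1142 at an unadjusted p under 0.05). Without male C26 trained 1, 18 genes differed by sex, among them, chosen after the values were seen, the amino acid transporter Slc38a2 (1.74 ± 0.27, higher in females, adjusted p = 0.0129) and the G-protein regulator Rgs2 (-3.31 ± 0.52, lower in females, adjusted p = 0.0129). The count in males was 3722 without male C26 trained 1, 273 without male C26 sedentary 2, 1104 without male PBS sedentary 1, 1061 in a fit of its own groups and 3771 with array weights. In females it was 3500 with array weights, 2729 without male C26 trained 1, 662, 726 and 746 without female PBS sedentary 1, 2 and 3, and 448 and 796 without female C26 sedentary 1 and 3. For the sex difference it was 169 with array weights, 1 without male PBS sedentary 1, 19 without male PBS sedentary 3, 1 without male C26 sedentary 1 and 9 without female C26 sedentary 2.

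The next comparison asked what training did in mice without a tumour (6 trained against 6 sedentary PBS libraries). No gene passed the adjusted threshold (limma, 1918 genes at an unadjusted p under 0.05), while the lists of oxidative phosphorylation, of fatty acid oxidation and of slow fibres passed as groups at the preset correlation but not with an estimated one (each adjusted p = 0.425). The slow myosin Myh7 was at 2.86 ± 0.88 (adjusted p = 0.194), from 3308 ± 2805 to 11169 ± 2920 normalized counts in males and from 6676 ± 7867 to 23100 ± 2985 in females (SD, n = 3 each). The oxidative fast myosin Myh2 was at 1.49 ± 0.59, Myh1 at 0.99 and the glycolytic fast myosin Myh4 at -0.56 ± 0.24. The coactivator Ppargc1a was at 1.07 ± 0.44 (adjusted p = 0.297), Pdk4, which restrains pyruvate oxidation, at 1.32 ± 0.50 and Vegfa at 0.43 ± 0.12 (adjusted p = 0.157).

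Of 15 slow and oxidative fibre genes 0 passed over all genes and 12 were higher when adjusted over the list alone (median 1.76, camera adjusted p = 3.46e-10, adjusted p = 0.425 with an estimated correlation). For the 64 oxidative phosphorylation genes 55 were higher adjusted over the list alone (median 0.33, camera adjusted p = 5.8e-29, adjusted p = 0.425 with an estimated correlation). Atp5b of ATP synthase was at 0.34 ± 0.13. Fatty acid uptake and oxidation had 25 of 27 higher adjusted over the list alone (median 0.56, camera adjusted p = 3.61e-16, adjusted p = 0.425 with an estimated correlation). The fatty acid transporter Cd36 was at 0.56. For the citric acid cycle it was 12 of 17 (median 0.24, camera adjusted p = 2.37e-09, adjusted p = 0.425 with an estimated correlation). Glycolysis genes (median -0.19, camera adjusted p = 0.000389, adjusted p = 0.429 with an estimated correlation, 1 higher and 3 lower of 23 adjusted over the list alone) went down as a list. So did fast fibre genes (median -0.23, camera adjusted p = 0.000259, adjusted p = 0.538 with an estimated correlation, 0 adjusted over the list alone). Amino acid catabolism (median 0.20, camera adjusted p = 0.000439, adjusted p = 0.44 with an estimated correlation, 5 higher and 1 lower of 21 adjusted over the list alone) and mitochondrial regulators (median 0.19, camera adjusted p = 0.00427, adjusted p = 0.44 with an estimated correlation, 1 higher and 1 lower of 27 adjusted over the list alone) went up as lists. The same held for endothelial markers (median 0.19, camera adjusted p = 0.00894, adjusted p = 0.538 with an estimated correlation, 0 adjusted over the list alone) and adipocyte markers (median 0.15, camera adjusted p = 0.0119, adjusted p = 0.466 with an estimated correlation, 3 of 12 higher adjusted over the list alone). The atrophy list also went up (median 0.25, camera adjusted p = 0.0255, adjusted p = 0.551 with an estimated correlation, 2 of 25 higher adjusted over the list alone). The interleukin-6 list did not pass (median -0.10, camera adjusted p = 0.649, 0 of 25 adjusted over the list alone).

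Slow-fibre genes varied between libraries of a group. The list's mean log2 value was 10.8, 7.54 and 11.03 in the male PBS sedentary libraries and 11.9, 11.9 and 11.5 in the trained ones, and 10.5, 8.65 and 11.8 against 12.5, 11.8 and 12.1 in females. The difference, 1.90 over both sexes, had an exact two-sided permutation p of 0.01 within sex, where the 400 arrangements allow 0.005. The count of 0 genes became 206 without male C26 trained 1, 380 without male PBS sedentary 3, 17 without female PBS sedentary 3. It became 149 in a fit of the PBS groups only, 118 with the replicate number as a block and 2538 with array weights. Among the 206, chosen after the values were seen, were the calcium pump regulator Sln (2.31 ± 0.52, adjusted p = 0.0402), Dgat2 of triglyceride synthesis (1.69), the myosin light chain Myl6b (1.53). Lower were the growth factor Igf1 (-1.06 ± 0.18, adjusted p = 0.0211), and Smox (-1.39 ± 0.20) and Amd1 (-1.23 ± 0.23) of polyamine metabolism. No gene passed in PBS males (limma, 1533 at an unadjusted p under 0.05) or in PBS females (limma, 596). In males the count was 11 without male C26 trained 1, 388 without male PBS sedentary 3 and 2417 with array weights, and in females it was 0 with each compared library left out and 4 with array weights.

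**Figure D3:**
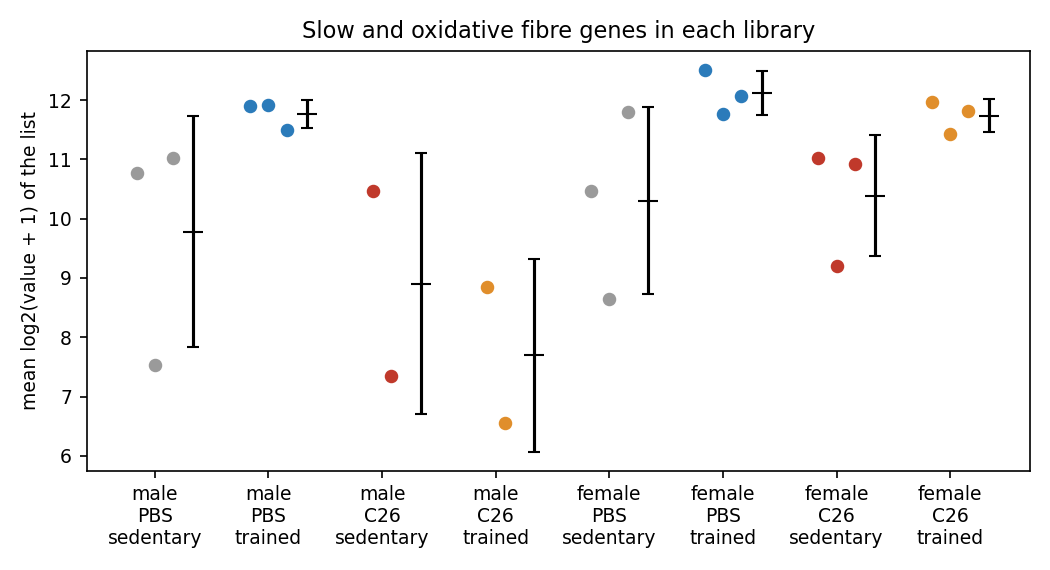
Mean log2 value of the 15 slow and oxidative fibre genes in each of the 22 libraries, by group, with the mean ± SD of each group as a black bar. PBS trained libraries lie between 11.5 and 12.5, and the male PBS sedentary libraries between 7.54 and 11.03.

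The following comparison asked what training did to tumour-bearing muscle (5 trained against 5 sedentary C26 libraries). Mettl21e, a protein methyltransferase of muscle, rose by 2.44 ± 0.32 (adjusted p = 0.0016), Ighm by 2.41 ± 0.44, Nmrk2 by 1.91 ± 0.42 (adjusted p = 0.0142), Nrep by 1.70 ± 0.34. The water channel Aqp4 rose by 1.69 ± 0.35, the cardiac actin Actc1 by 1.67 ± 0.34, Ostn by 1.59 ± 0.45 and the thioesterase Acot11 by 1.55. The metallothioneins Mt2 (-3.11 ± 0.45, adjusted p = 0.00267) and Mt1 (-2.57 ± 0.48), Lcn2 (-2.51 ± 0.55, adjusted p = 0.0144) and the matrix protease Mmp3 (-2.45 ± 0.42) fell. So did Rsc1a1 (-3.66 ± 1.06), the macrophage lectin Clec10a (-2.96 ± 0.79), Csrnp1 (-2.75) and the matrix gene Fbln1 (-2.68). The last 3 were listed at 0 in male C26 trained 1, and without that library they were at -1.31, -1.35 (adjusted p = 0.0882) and -1.09, while Acot11 had an adjusted p of 0.0632. Rsc1a1 stood near 0 in female C26 trained mice (0.777 ± 1.34 normalized counts, SD, n = 3), so its fold change depends on the added count. The calls of Ostn, Rsc1a1 and Csrnp1 ended with the replicate block. Mt2 went from 3653 ± 1223 to 719 ± 572 normalized counts in males (SD, n = 2 each) and from 3517 ± 2144 to 236 ± 37.4 in females (n = 3 each). Over all genes 440 rose and 454 fell (limma). Of the 80 named genes that passed, 72 lay on that side in each of the 5 trained libraries. The exceptions were Csrnp1, Lcn2, Hp, Map1lc3b, Nog, Pdgfrb and Pck1, in 4 of 5, and Utp20, in 3 of 5.

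Acute phase genes fell and genes of energy metabolism rose. In the interleukin-6, STAT3 and acute phase list 11 of 25 fell (median -0.92, camera adjusted p = 3.6e-08, adjusted p = 0.311 with an estimated correlation, 15 adjusted over the list alone). Serpina3n was at -1.91 ± 0.36 and Stat3 at -0.92 ± 0.15 (adjusted p = 0.00392). Of 64 oxidative phosphorylation genes 19 rose (median 0.38, camera adjusted p = 6.71e-25, adjusted p = 0.425 with an estimated correlation, 43 adjusted over the list alone), with Ndufs1 at 0.7 ± 0.13. Of 17 citric acid cycle genes 12 rose (median 0.45, camera adjusted p = 2.93e-14, adjusted p = 0.354 with an estimated correlation, 15 adjusted over the list alone), with Dlat at 0.84 ± 0.12. Mitochondrial regulators had 6 of 27 higher (median 0.31, camera adjusted p = 0.000196, adjusted p = 0.416 with an estimated correlation, 9 higher and 1 lower adjusted over the list alone). The mitochondrial transcription factor Tfam was at 0.51. In males alone the median was -0.09 for mitochondrial regulators, 0.22 for oxidative phosphorylation and 0.17 for the citric acid cycle, each with 0 genes called. Glycolysis had 4 higher and 1 lower of 23 (median 0.24, camera adjusted p = 3.71e-05, adjusted p = 0.425 with an estimated correlation, 8 and 1 adjusted over the list alone), with Pkm at 0.52. Calcium handling had 2 of 22 higher (median 0.22, camera adjusted p = 0.000226, adjusted p = 0.538 with an estimated correlation, 2 adjusted over the list alone), with Casq1 at 1.03. Amino acid catabolism had 4 of 21 higher (median 0.17, camera adjusted p = 5.68e-05, adjusted p = 0.425 with an estimated correlation, 5 adjusted over the list alone). Fast fibre genes had 3 of 15 higher (median 0.15, camera adjusted p = 0.00894, adjusted p = 0.626 with an estimated correlation, 4 adjusted over the list alone). The share of mitochondrial transcripts was 17.6% to 18.5% in the female trained libraries and 11.1% to 14.2% in the female sedentary ones, and in males it was 9.26% and 10.8% in the trained and 10.6% and 10.7% in the sedentary libraries.

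Genes of protein breakdown depended on male C26 trained 1. The atrophy list had 4 lower and 1 higher of 25 (median -0.37, camera adjusted p = 0.0332, adjusted p = 0.573 with an estimated correlation, 4 and 1 adjusted over the list alone), and without that library 11 lower (median -0.58, camera adjusted p = 1.17e-06, adjusted p = 0.262 with an estimated correlation). The fit without that library leaves a single mouse in the male C26 trained group, with a spread taken from the other groups. Trim63 was at -1.04 ± 0.51 (adjusted p = 0.178) with male C26 trained 1 and at -1.83 without it. Fbxo32 was at -0.84 ± 0.39 (adjusted p = 0.159) with it and at -1.35 without it. Proteasome subunits had 1 of 32 lower (median -0.10, camera adjusted p = 0.0983, 1 adjusted over the list alone) and 8 without it (median -0.18, camera adjusted p = 3.32e-07, adjusted p = 0.445 with an estimated correlation). The NRF2 list had 5 lower and 1 higher of 24 (median -0.28, camera adjusted p = 0.0434, adjusted p = 0.538 with an estimated correlation, 8 and 2 adjusted over the list alone). Ribosome biogenesis had 3 of 26 lower (median -0.20, camera adjusted p = 0.0331, adjusted p = 0.626 with an estimated correlation, 4 adjusted over the list alone), with Myc at -1.35 ± 0.31. The extracellular matrix had 1 of 34 lower (median -0.29, camera adjusted p = 0.045, adjusted p = 0.739 with an estimated correlation, 5 adjusted over the list alone). Macrophage markers had 3 of 13 lower (median -0.39, camera adjusted p = 0.0525, 4 adjusted over the list alone), with Cd163 at -1.19 ± 0.19 and the mannose receptor Mrc1 at -1.33 ± 0.22. Without that library 2 were lower (median -0.50, camera adjusted p = 0.000282, adjusted p = 0.445 with an estimated correlation). Slow fibre genes (median 0.11) and fatty acid oxidation (0.10) did not pass, with 0 members each over all genes and adjusted over the list alone. In males alone the medians were -1.19 and -0.19. The slow list's mean log2 value was 10.46 and 7.34 in male C26 sedentary libraries and 8.85 and 6.55 in male C26 trained ones. In females it was 11.03, 9.21 and 10.92 in sedentary and 11.96, 11.43 and 11.82 in trained C26 libraries. The trained libraries were higher in females, while in males the sedentary and trained values overlapped. A sex difference of this list was not tested.

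The count for training in tumour-bearing mice moved with single libraries. It was 1214 without male C26 trained 1, of which 561 were shared, 7613 without male C26 trained 2, 87 without male C26 sedentary 2, 416 without female C26 sedentary 1, and 462, 458 and 588 without female C26 trained 1, 2 and 3. A fit of the 4 C26 groups alone called 14 genes, and Serpina3n, Stat3, Mt2 and Nmrk2 were not among them. Array weights, which gave both male C26 trained libraries a weight of 0.0485, called 0 genes (1107 at an unadjusted p under 0.05). Leaving out 1 library ended between 3 and 808 of the 894 calls.

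Sex was tested in the same mice. In females Hp (-4.53 ± 0.65, adjusted p = 0.00232), Lcn2 (-3.98 ± 0.69) and Mt2 (-3.65 ± 0.58) fell. Mettl21e rose by 2.38 ± 0.41 and Ighm by 2.54 ± 0.56. In males Hes1, a Notch target repressor, was at -2.81 ± 0.40 (adjusted p = 0.0126), Rgs2 at -2.87 ± 0.48 and Csrnp1, listed at 0 in male C26 trained 1, at -5.37 ± 1.17. The coactivator Cited4 rose by 2.25 ± 0.35 and the mitochondrial folate enzyme Mthfd2 by 2.08 ± 0.37. In the fit without male C26 trained 1, where male C26 trained 2 stands alone and is assumed to vary like the other groups, the male calls of Hes1 (-2.61 ± 0.46, adjusted p = 0.0203), Rgs2 and Cited4 passed, and those of Csrnp1 (adjusted p = 0.155) and Mthfd2 (adjusted p = 0.059) ended. The fit called 310 higher and 199 lower in females and 29 higher and 74 lower in males. Each of the 60 named genes that passed in females lay on that side in all 3 trained libraries and each of the 15 in males in both. The sex by training difference was called for 2 genes (limma, 3044 at an unadjusted p under 0.05), Hes1 (3.51, more positive in females) and Ppp1r14b (-1.13), and for 0 without male C26 trained 1. The female count was 1943 with array weights, 1383 without male C26 trained 1, 122 without female C26 sedentary 1, and 146, 164 and 178 without female C26 trained 1, 2 and 3. The male count was 67 without male C26 trained 1 (14 shared), 8081 without male C26 trained 2, 0 without male C26 sedentary 2, 52 with the block, 0 in a fit of its own groups (258 at an unadjusted p under 0.05) and 0 with array weights (879). The sex by training count was 7495 without male C26 trained 2, 6 without female C26 sedentary 3, and 0 without male C26 sedentary 2, female C26 sedentary 1 or 2, or any female C26 trained library. It was also 0 with the block, in a fit of its own groups and with array weights (3099, 926 and 870 at an unadjusted p under 0.05), and 1 without the filter.

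The tumour response score set the 2 comparisons against each other with genes picked in the other sex. It was 0.84 ± 0.18 in male C26 sedentary and 0.48 ± 0.19 in male C26 trained libraries (SD, n = 2 each), and 0.62 ± 0.12 and 0.19 ± 0.03 in the female groups (n = 3 each). PBS trained mice scored -0.03 in males and -0.00096 in females. The difference was -0.40 over both sexes (exact two-sided permutation p = 0.0167, the smallest that 120 arrangements can give), with -0.36 in males and -0.43 in females. In males it was -0.04 without male C26 trained 2 and -0.21 without male C26 sedentary 2. Of the 1788 genes called for the tumour in sedentary males, 1611 (90.1%) had the opposite sign for training in tumour-bearing females, and of the 1253 called in females 1048 (83.6%) had the opposite sign in males. Over all genes the fold changes correlated at r = -0.494 and -0.113 in the same order, against -0.765 and -0.593 over the called genes. Of the called genes, 135 were higher with the tumour in males and lower with training in females, and 187 the reverse, where independent lists would share 12.7 and 18.4, while 1 was called in the same direction in both. Without male C26 trained 2 the score difference was -0.20 (exact p = 0.0667), without male C26 sedentary 2 it was -0.40 (exact p = 0.0333), and over the other alternatives its p stayed at 0.0167. With the 100 genes of smallest p in the other sex it was -0.74.

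**Figure D4:**
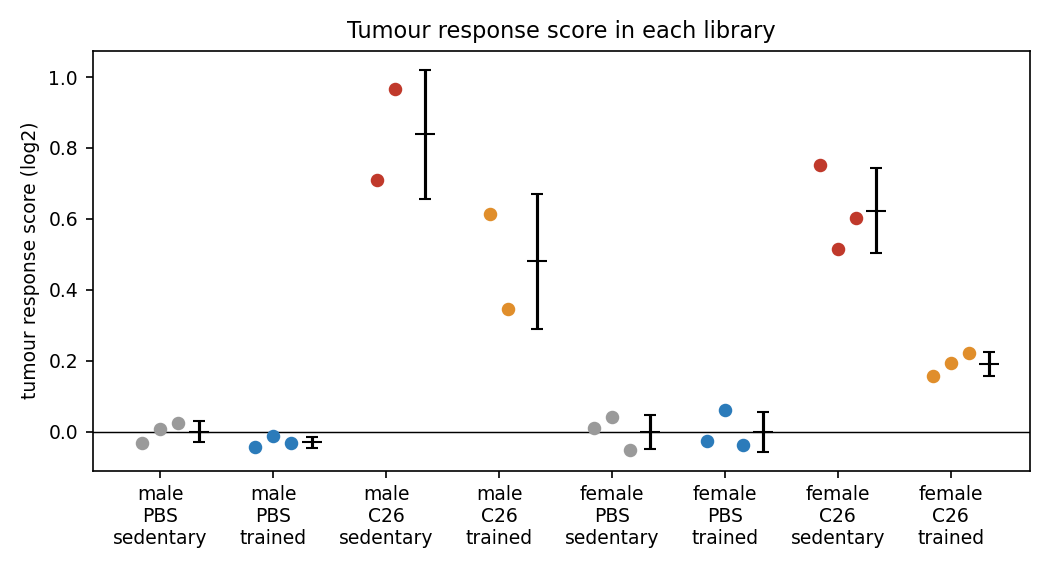
Tumour response score of each of the 22 libraries (signed mean log2 change over the genes called in the other sex), by group, with the mean ± SD of each group as a black bar. Female C26 sedentary libraries lie between 0.52 and 0.75 and female C26 trained libraries between 0.16 and 0.22.

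The tumour was also compared with PBS among trained mice (5 C26 against 6 PBS libraries). Lcn2 rose by 3.56 ± 0.52 (adjusted p = 0.000961), Mt2 by 2.71 ± 0.43, Serpina3n by 2.53 ± 0.34 (adjusted p = 0.000741), Socs3 by 2.39 ± 0.40 and the adhesion molecule Selp by 2.19 ± 0.42. The embryonic myosin Myh3 (-3.67 ± 0.57, a fit that depends on the added count, since both male C26 trained libraries listed it at 0), Cilp2 (-3.6 ± 0.61), Chad (-3.56 ± 0.54), the slow myosin Myh7 (-3.50 ± 0.93, adjusted p = 0.0215) and the collagen-binding Fmod (-3.72 ± 0.96) were lower. Trim63 (0.77 ± 0.48, adjusted p = 0.234) and Fbxo32 (0.71, adjusted p = 0.156) did not pass. The fit called 694 genes higher and 1706 lower, and without male C26 trained 1 it called 296 higher and 945 lower, with 962 shared. Of 113 named genes that passed, 92 lay on that side in each of the 5 C26 libraries, while the other 21 did so in 2 to 4. Selp did so in 4, Lgals4, Hk2, Bop1, Cth and Mccc1 in 3, and Dld and Acadm in 2. Cish (2.03), Mt1 (1.92), myostatin (1.07) and Lgals4 (-2.35) passed with male C26 trained 1, and without it their adjusted p was 0.0567, 0.0635, 0.133 and 0.156. Fmod was listed at 0 in that library and lay at -1.62 ± 0.45 without it.

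Among trained mice, slow fibre genes, the matrix and acute phase genes differed. Of 15 slow fibre genes 11 fell (median -2.51, camera adjusted p = 0.000236, adjusted p = 0.593 with an estimated correlation, 13 adjusted over the list alone), with Myl2 at -3.18 and Myh2 at -2.55 ± 0.63. Myh7 stood at 196 and 108 normalized counts in the male C26 trained libraries, against 8721 to 14402 in male PBS trained ones, and at 13744 ± 3293 and 23100 ± 2985 in the corresponding female groups (SD, n = 3 each). Of 34 extracellular matrix genes 22 fell and 1 rose (median -0.69, camera adjusted p = 3.02e-09, adjusted p = 0.425 with an estimated correlation, 29 and 1 adjusted over the list alone), with Col1a1 at -1.15 (not called in a fit of the trained groups only, nor was Fmod). Of 10 tendon markers 9 fell (median -2.95, camera adjusted p = 2.8e-06, adjusted p = 0.425 with an estimated correlation, 9 adjusted over the list alone), with tenomodulin (Tnmd) at -2.97. Acute phase genes had 14 of 25 higher (median 1.0, camera adjusted p = 1.79e-12, adjusted p = 0.295 with an estimated correlation, 16 adjusted over the list alone). Neutrophil markers had 3 of 5 higher (median 2.53, camera adjusted p = 3.71e-05, adjusted p = 0.311 with an estimated correlation, 4 adjusted over the list alone), and proteasome subunits 12 of 32 (median 0.30, camera adjusted p = 3.39e-12, adjusted p = 0.416 with an estimated correlation, 22 adjusted over the list alone). Fatty acid oxidation had 8 of 27 lower (median -0.52, camera adjusted p = 0.000142, adjusted p = 0.652 with an estimated correlation, 18 adjusted over the list alone). Oxidative phosphorylation had 14 of 64 lower (median -0.34, camera adjusted p = 9.41e-08, adjusted p = 0.651 with an estimated correlation, 43 adjusted over the list alone). Endothelial markers had 7 of 13 lower (median -0.45, camera adjusted p = 0.00154, adjusted p = 0.466 with an estimated correlation, 8 adjusted over the list alone), with the growth factor receptor Kdr at -1.57 ± 0.17. In females the medians of the slow fibre, matrix, tendon and acute phase lists were -0.44, -0.42, -0.54 and 0.67. In males they were -4.59, -0.96, -5.26 and 1.37. For neutrophils, proteasome, fatty acid oxidation, oxidative phosphorylation and endothelium they were 2.68, -0.02, 0.03, -0.09 and -0.03 in females. The male values were 3.055, 0.56, -1.08, -0.63 and -0.83. In females only 1 acute phase gene was called among these lists.

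Within sex, the trained tumour comparison rested on few libraries. In females 1 gene passed (limma, 767 at an unadjusted p under 0.05), Osmr, which rose by 1.19 ± 0.16 (adjusted p = 0.0166) in 3 of 3 libraries and was not called in a fit of the 6 trained female libraries. In males 1612 genes were higher and 4207 lower, with Lcn2 at 5.57 ± 0.77 and Fmod at -6.92 ± 1.43. Myh3 was listed at 0 in both male C26 trained libraries and stood at 99.5 ± 35.6 normalized counts in male PBS trained ones (SD, n = 3). Without male C26 trained 1 the male count was 1355 (1110 shared), 552 of the 5819 genes had the opposite sign, and Fmod was at -2.73. The sex difference of this comparison was not tested. The sex-averaged count was 1259 in a fit of the trained groups only, 8647 without male C26 trained 2, 1151 and 1246 without male PBS trained 1 and 2, 1386 and 1257 without female PBS trained 1 and 3, and 1524, 1256 and 1350 without female C26 trained 1, 2 and 3. The male count was 9444 without male C26 trained 2, 3374 and 3486 without male PBS trained 1 and 2, and 89 in a fit of its own groups. The female count was 367 with array weights, 2 with a mean of at least 50, 7 without male C26 trained 1, 5 in a fit of its own groups, 0 without female PBS trained 1 or 2 or female C26 trained 2 or 3, and 2 without female PBS trained 3. Array weights called 0 genes in the sex-averaged and male comparisons (1570 and 1308 at an unadjusted p under 0.05). Leaving out 1 library ended between 68 and 1438 of the 2400 sex-averaged calls.

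The interaction asked whether training and the tumour combined otherwise than by adding up (22 libraries, sexes averaged). Ostn was 3.11 ± 0.60 higher than the sum of both effects (adjusted p = 0.029), Nmrk2 2.91 ± 0.56, Ighm 2.76 ± 0.59, Mettl21e 2.07 ± 0.43 and Amd1 of polyamine synthesis 1.97 ± 0.41. Mt1 (-3.08 ± 0.64), Mt2 (-3.01 ± 0.61), Togaram2 (-2.46 ± 0.59), Serpina3n (-2.29 ± 0.49) and Cpxm1 (-2.12 ± 0.43) were lower than the sum. Nmrk2 stood at 4711 ± 1115 and 1699 ± 501 normalized counts in sedentary and trained PBS males (SD, n = 3 each) and at 131 ± 89.1 and 525 ± 358 in male C26 sedentary and trained mice (n = 2 each). The fit called 98 genes higher and 106 lower, and all 34 named genes that passed lay on that side of the sum in each of the 5 C26 trained libraries. Plin4 (-1.0 ± 0.16, adjusted p = 0.0144), the proteasome subunit Psma7 (-0.65 ± 0.11, adjusted p = 0.025), the glycolytic enzyme Pgk1 (0.60 ± 0.11), Stat3 (-1.03 ± 0.20) and Cd163 (-1.28 ± 0.25) also passed.

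Among lists, glycolysis had 3 of 23 called higher (median 0.51, camera adjusted p = 5.32e-08, adjusted p = 0.312 with an estimated correlation, 13 higher and 2 lower adjusted over the list alone). Acute phase genes had 4 of 25 lower (median -1.09, camera adjusted p = 2.33e-06, adjusted p = 0.354 with an estimated correlation, 14 adjusted over the list alone). The atrophy list had 4 of 25 lower (median -0.52, camera adjusted p = 0.00248, adjusted p = 0.44 with an estimated correlation, 8 lower and 1 higher adjusted over the list alone), and 11 without male C26 trained 1. Without that library, which leaves a single mouse in the male C26 trained group, Trim63 was at -2.49 and Fbxo32 at -2.04. With male C26 trained 1 they were at -1.69 (adjusted p = 0.202) and -1.53 (adjusted p = 0.142). Calcium handling (median 0.31, camera adjusted p = 1e-05, adjusted p = 0.44 with an estimated correlation, 0 called, 2 of 22 higher adjusted over the list alone) went up as a list. So did fast fibre genes (median 0.35, camera adjusted p = 1.28e-05, adjusted p = 0.44 with an estimated correlation, 1 called, 5 of 15 higher adjusted over the list alone). Slow fibre genes (median -2.02, camera adjusted p = 0.0075, adjusted p = 0.699 with an estimated correlation, 0 called and 0 adjusted over the list alone) went down. Adipocyte markers (median -0.95, camera adjusted p = 0.00331, adjusted p = 0.425 with an estimated correlation, 2 called, 3 of 12 lower adjusted over the list alone) went down as well. So did macrophage markers (median -0.54, camera adjusted p = 0.0114, adjusted p = 0.538 with an estimated correlation, 1 called, 5 of 13 lower adjusted over the list alone). The interaction count was 742 without male C26 trained 1, with 198 shared, and 6423 without male C26 trained 2. It was 4 without male C26 sedentary 2, and 16, 42 and 478 without male PBS sedentary 1, 2 and 3, and 14, 13 and 45 without male PBS trained 1, 2 and 3. In females it was 32, 40 and 99 without PBS sedentary 1, 2 and 3, 128, 11 and 32 without PBS trained 1, 2 and 3, 39, 505 and 17 without C26 sedentary 1, 2 and 3, and 14, 12 and 37 without C26 trained 1, 2 and 3. Array weights called 0 genes (1409 at an unadjusted p under 0.05), and the call of Togaram2 ended without the filter.

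**Figure D5:**
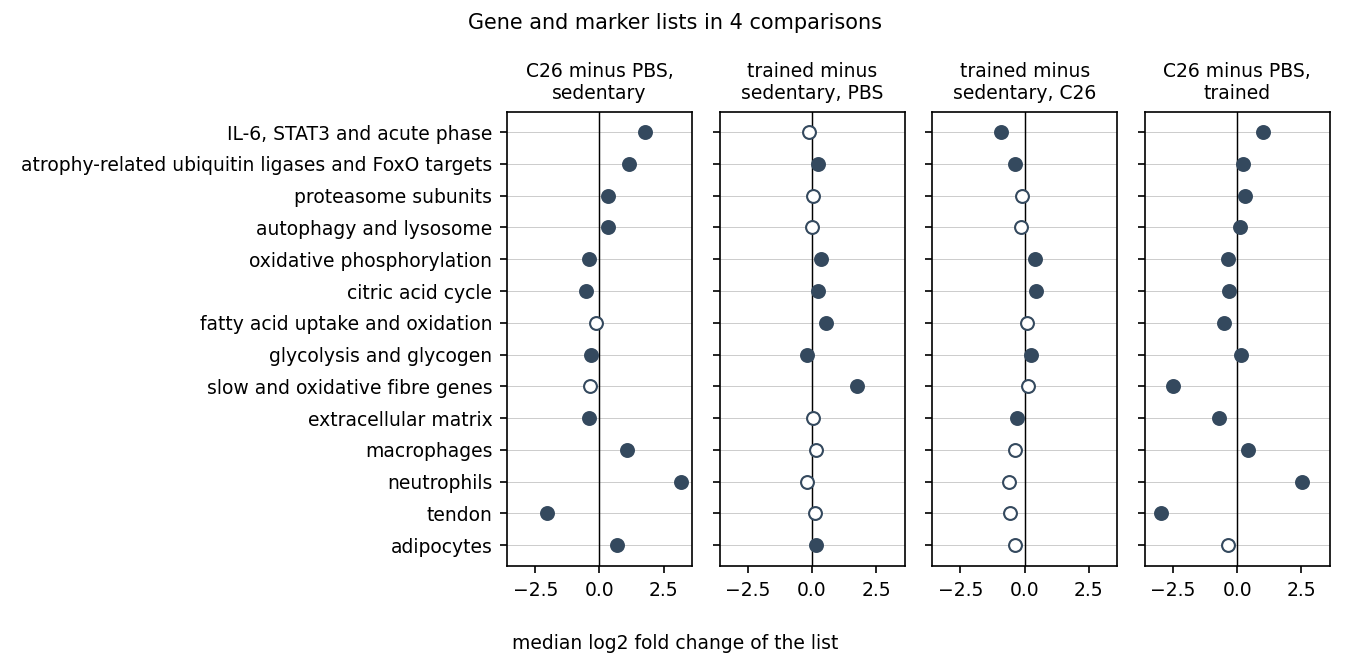
Median log2 fold change of 14 gene and marker lists in 4 sex-averaged comparisons (tumour in sedentary and in trained mice, training in PBS and in tumour-bearing mice), filled where the camera adjusted p at the preset correlation was under 0.05 and open elsewhere. The interleukin-6, STAT3 and acute phase list lies at 1.78 for the tumour in sedentary mice and at -0.92 for training in tumour-bearing mice.

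Sexes differed without tumour or training as well (3 female against 3 male PBS sedentary libraries). The secreted hormone Stc2 was 1.87 ± 0.30 higher in females, Zfp503 1.76, Itm2a 1.04, the cytoskeletal Obsl1 0.91 ± 0.10 and Klhl33 0.90, and Slc15a5 was lower (-6.04). The fit called 12 genes higher and 40 lower in females. The Y-linked genes Ddx3y, Kdm5d and Uty were listed at 0 in all 12 female libraries, and Eif2s3y at 0 in 11 of them and at 1.09 in female PBS sedentary 3. Ddx3y stood at 904 to 1690 normalized counts in the 10 male libraries, and Kdm5d was listed at 0 in male C26 trained 1 only. Xist, the transcript of the inactive X chromosome, stood at 2041 to 2882 in 11 female libraries and at 0 in female PBS sedentary 3. The count of 52 genes was 170 without male C26 trained 1, 30, 24 and 151 without male PBS sedentary 1, 2 and 3, 27, 31 and 32 without female PBS sedentary 1, 2 and 3, and 1230 with array weights.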

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

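The tests of the read number and of the most abundant genes of male C26 trained 1 were chosen only after the result was seen, and so were the counts of the sex-averaged tumour and PBS comparisons without that library.

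The effect of training differed between PBS and tumour-bearing mice for 204 genes in the test of the difference itself. The genes with the largest differences were Ostn (3.11), Nmrk2 (2.91), Ighm (2.76), Mettl21e (2.07) and Amd1 (1.97), more positive with the tumour, and Mt1 (-3.08), Mt2 (-3.01), Togaram2 (-2.46), Serpina3n (-2.29) and Cpxm1 (-2.12), more negative. Without a filter on low values the call of Togaram2 ended. In 1 of 100 splits of the libraries, the real one, the count was as large (204 genes against 144 in the highest other split). These 100 were drawn from 24000 possible splits. Such splits can carry the training effect itself, as in the female fit below, so whether chance accounts for the count stays open. Without male C26 trained 1, 1 of 100 splits was as large, with 742 genes against 61 in the highest other.

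The effect of training in tumour-bearing mice differed between the sexes for 2 genes in the test of the difference, Hes1 (3.51) and Ppp1r14b (-1.13). Hes1 stood at 307 and 446 normalized counts in male C26 sedentary libraries, at 45 and 59.5 in male C26 trained ones, at 89.8 to 170 in female C26 sedentary and at 170 to 209 in female C26 trained ones. Ppp1r14b stood at 442 and 488, 700 and 801, 353 to 369, and 242 to 278 in the same order. Both calls ended without male C26 trained 1 (adjusted p = 0.0731 and 0.0769, limma), where the differences were 3.31 ± 0.56 and -1.04 ± 0.19 against 3.51 ± 0.51 and -1.13 ± 0.17 (SE) with it, so they moved by less than their SE. That library listed Hes1 at 45, next to 59.5 in the other library of its group. Both calls also ended without female C26 sedentary 1 or 2, and without any of the female C26 trained libraries. They ended too with the replicate block, with array weights and in a fit of the compared groups only.

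Male C26 trained 1 listed 5730 genes at 0, where the 21 other libraries listed 173 to 644. Fewer reads are argued against, since its estimated 16.6 M reads (M, 1e6) lay inside the range of the others, 12.2 to 20.8 M, and so is a library taken up by a few genes, since its 10 most abundant genes held 25.1% of its total against 22.2% to 27.4%. A candidate explanation that passed a test which could have gone the other way is a library made from few starting molecules, each copied many times. The share of its genes at 0 fell from 51.1% to 22.4% and 4.39% over mean values of 20 to 60, 60 to 150 and 150 to 400, which correspond to 52.9, 63.4 and 72.5 reads per molecule, and the highest of these was 1.37 times the lowest. Of the 7779 genes with at least 100 normalized counts in each of the other 21 libraries, it listed 110 at 0. No biological explanation was tested, and how it was prepared stays open.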

How the results depend on the processing

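The fits without male C26 trained 1 for comparisons that do not hold it, the tests of the 12 female libraries and the gene-by-gene estimator of array weights were chosen only after the results were seen. Of 345 alternative values of the counts, the list tests and the score, 199 stayed within 1.5 times or on the same side of the threshold and 146 did not, and of 12380 values of single genes 10214 kept their call, 2163 lost it and 3 changed sign, with 366 lost under array weights and 275 in fits of the compared groups only. Leaving out 1 library ended between 3 of 366 calls (male C26 trained 2) and 182 of 338 (male C26 sedentary 2), and 123 of 738 for male C26 trained 1. The 3 changes of sign were for the tumour in trained males, where with each library left out Mcm2 ranged from -4.31 to 0.20, Kdm5d from -7.59 to 0.41 and Acvr2b from -5.06 to 0.30, the lowest without male C26 trained 2 and the highest without male C26 trained 1. Over all genes that fit without male C26 trained 1 ended 4708 of 5819 calls and turned the sign of 552. With array weights the counts were 5439 (tumour, sedentary mice), 2538 (training, PBS mice), 0 (training, tumour-bearing mice), 0 (tumour, trained mice) and 0 (interaction), then 3771 and 3500 for the tumour in sedentary males and females, 2417 and 4 for training in PBS males and females, 0 and 1943 for training in tumour-bearing males and females, 0 and 367 for the tumour in trained males and females, 169 for sex by tumour, 0 for sex by training and 1230 for the sex difference. The weights were 0.0485 for both male C26 trained libraries, which a group of 2 weights equally since it cannot show which library deviates, and 4.38 for male PBS sedentary 1. In fits of the compared groups only, with fewer libraries to estimate the variance, the counts were 149 (training, PBS mice), 14 (training, tumour-bearing mice), 1259 (tumour, trained mice), 1061 (tumour, sedentary males), 0 (training, tumour-bearing males), 89 and 5 (tumour, trained males and females) and 0 (sex by training). With the replicate number as a block they were 118 (training, PBS mice), 52 (training, tumour-bearing males) and 0 (sex by training). The main fit did not treat these numbers as pairs. A mean of at least 50 gave 2 genes for the tumour in trained females and no filter gave 1 for sex by training. With each library of the compared groups, or male C26 trained 1, left out in turn, the counts ranged from 1671 to 5251 (tumour, sedentary mice), 0 to 380 (training, PBS mice), 87 to 7613 (training, tumour-bearing mice), 1151 to 8647 (tumour, trained mice), 4 to 6423 (interaction), 273 to 3722 and 448 to 2729 (tumour, sedentary males and females), 0 to 388 and 0 to 0 (training, PBS males and females), 0 to 8081 and 122 to 1383 (training, tumour-bearing males and females), 1355 to 9444 and 0 to 7 (tumour, trained males and females), 0 to 19 (sex by tumour), 0 to 7495 (sex by training) and 24 to 170 (sex difference). The highest counts above 0 came without male C26 trained 2, which leaves male C26 trained 1 alone in its group with a spread taken from the other groups, without male C26 trained 1, which likewise leaves male C26 trained 2 alone, or without male PBS sedentary 3. A fit without either male C26 sedentary library leaves the other alone in the same way. Of 180 list tests, 80 passed, 0 passed with an estimated correlation, 51 with fry, 87 without male C26 trained 1 and 0 without it and with an estimated correlation. The score difference was negative in all its alternatives. It was -0.74 with the 100 genes of smallest p in the other sex, and with each library of its groups left out it ranged from -0.48 without male C26 sedentary 1 to -0.20 without male C26 trained 2, where its exact p was 0.0667 and the difference in males -0.04. For the 12 female libraries, with the variance taken from all 22 libraries, the counts were 1253 (tumour, sedentary), 509 (training, tumour-bearing) and 5 (interaction), and the interaction had 98 with all but male C26 trained 1. In the fit of these 12 libraries alone, where the counts were 2791, 1409 and 15, leaving out each female library gave ranges of 1481 to 3643, 601 to 1840 and 0 to 697. Except where stated, the cause was not tested. Count tests with edgeR and DESeq2 were planned for whole reads and were not run, since whole reads were not recovered, and depth limits genes below a mean of 10, which were left out of the fit.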

Other observations

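The tests on the 12 female libraries and those on the slow-fibre genes and on the Y-linked and X-linked genes, other than that of a single X chromosome, were chosen only after the results were seen.

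In the 12 female libraries fitted alone, 15 genes passed for the training by tumour interaction, and those named here were chosen after their values were seen. Hp was -5.01 ± 0.68 from the sum of both effects (adjusted p = 0.027, limma) and stood at 44.3, 65.3, 1790 ± 1062 and 69.9 normalized counts in PBS sedentary, PBS trained, C26 sedentary and C26 trained females (SD, n = 3 each). Fcna, a ficolin of macrophages, was at -2.22 ± 0.31, with 28.6 ± 7.03, 34.1, 194 ± 38.4 and 48.9 ± 6.72, the hyaluronan receptor Lyve1 at -1.46 ± 0.21, the chemokine Ccl6 at -2.30 ± 0.33, the clotting factor subunit F13a1 at -1.39 ± 0.20, the scavenger receptor Stab2 at -1.37 ± 0.21 and the lipid carrier Apod at -2.16 ± 0.32. Alas1, the first enzyme of haem synthesis, was at 0.89 ± 0.15, with 2255, 2241, 1102 and 2019, and the aldo-keto reductase Akr1b10 at 1.09 ± 0.15. Of 13 macrophage markers 0 passed in this test (median -1.11; camera adjusted p = 8.87e-09, and adjusted p = 0.466 with an estimated correlation), and Cd163 stood at 185, 238, 652 and 278 and Mrc1 at 212, 216, 584 and 227 in the 4 groups.

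The female fit called 2791 genes for the tumour in sedentary mice, 1409 for training in tumour-bearing mice and 15 for the interaction. It called 0 for training in PBS mice (limma; 1364 at an unadjusted p under 0.05) and 0 for the tumour in trained mice (limma; 1831), and these counts were 23 without female PBS sedentary 3 and 49 without female C26 sedentary 2. Of 100 splits, 5 gave at least the 15 interaction genes, and the highest other gave 864. That split exchanged the activity labels of the C26 mice and so counted training over PBS and C26 females together, which the fit called for the same number of genes. The splits thus carry the training effect itself, which is the structure behind the 864 genes, and whether the 15 arose by chance stays open. The interaction count was 697 without female C26 sedentary 2, 43 without PBS trained 1, 8 without PBS sedentary 2, 1 without C26 trained 2 and 0 without each of the other 8 females. The tumour count was 1753 without PBS sedentary 1 and 1481 without C26 sedentary 1, and the training count was 601 without C26 sedentary 1 and 648, 647 and 648 without C26 trained 1, 2 and 3.

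Other splits of the libraries were counted for the remaining comparisons. For the tumour in sedentary mice 1 of 100 splits, the real one, was as large (3155 genes against 1750 in the highest other). These 100 were drawn from 200 possible splits. The share lies under 0.05, so the count argues against chance without excluding it. For training in tumour-bearing mice 2 of 60 splits were as large, a share under 0.05, but the highest other called 1628 genes against 894. In that split male C26 sedentary 2 and male C26 trained 2 changed places, and why it called more genes was not tested. With the female labels left as they were, that split can carry the training effect in females, so it does not stand for chance alone. Another grouping still gave more calls than the real one, so the count alone does not exclude chance. Without male C26 trained 1, 2 of 60 were as large (1214 genes, highest other 1442). For the tumour in trained mice 1 of 100 was as large (2400 genes, highest other 1941). Another grouping thus came near the real count. Within sex, 5819 genes were called in males and 1 in females, so the count leans on the 2 male C26 trained libraries. Splits without male C26 trained 1 leave male C26 trained 2 alone in its group and cannot settle this, so chance stays open. For training in PBS mice the real count was 0 and so was that of all 100 splits, so the count says nothing about chance. Splits of 3 against 3 libraries are too few, with 10 in each case. The real and highest other counts were 1253 and 0 for the tumour in sedentary females, 509 and 0 for training in tumour-bearing females, 52 and 0 for the sex difference, 1 and 1 for the tumour in trained females (2 of 10 splits), and 0 and 0 for training in PBS males and in PBS females (10 of 10 splits each).

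The slow-fibre genes were higher in trained PBS mice and very low in single libraries, such as male PBS sedentary 2 (7.54) and male C26 trained 2 (6.55, as a mean log2 value of 15 genes). In PBS mice the trained libraries were higher by 1.90 with an exact p of 0.01 within sex. This is the difference that drew attention to the list, so the test excludes nothing, and the slow part of the muscle taken at random amounts cannot be told apart from an effect of training. For the male C26 trained libraries, which were -4.07 from the PBS trained ones, such uneven amounts cannot be told apart from an effect of the tumour, since 10 arrangements give no exact p below the 0.1 observed. An uneven part of the muscle could therefore account for the low Myh7 of both, while a loss of slow fibres with the tumour stays open.

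Female PBS sedentary 3 listed Xist at 0. A male mouse under a female label is argued against by its 4 Y-linked genes, which summed to 1.09 normalized counts against 1785 to 3135 in 9 males. Male C26 trained 1, which listed the Y-linked Kdm5d at 0, was left out of the male ranges. A failed measurement of Xist alone is argued against by 4 genes that escape X inactivation (Kdm6a, Kdm5c, Ddx3x and Eif2s3x), whose mean log2 value lay -0.57 from the lowest other female and inside the male range of 9.41 to 9.99. A single X chromosome stays open: a separate pair of escaping genes, Pbdc1 and 5530601H04Rik, lay 0.23 above the lowest other female. The bound set for that pair was wrong, since the males reached 5.55, above the lowest other female at 5.35, so the pair does not separate the sexes.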
